A study of Mus musculus with 20 samples.

How the data were processed

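The series holds 20 samples from C57BL/6 mice, 10 RNA libraries and 10 libraries of antibody-derived tags (ADT, oligonucleotide-labelled antibodies that count surface proteins), from cells sorted out of 4 tissues. Per the labels' protocols, tissues were dissociated, leukocytes were enriched on Percoll, and CD45-positive, lineage-negative cells that carried NKp46 and NK1.1 were sorted and loaded on a droplet instrument for 3-prime single-cell RNA sequencing. The lineage gate removed cells with T cell, B cell, erythroid and macrophage surface markers. Per the submitters' processing notes, reads were processed with Cell Ranger 4.0.0 and the mouse build mm10. Any aligner setting beyond these is not given in the sources used here.

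The expression values deposited by the authors are on a natural log scale, ln(1 + UMIs per 10000 UMIs of the cell), in a separate table for each tissue with cells as columns. A UMI (unique molecular identifier) marks 1 captured RNA molecule. After undoing the log, every cell summed to 10000 in each table. Multiplying each value by the deposited total count of its cell gave whole numbers within 0.01 for 100% of values, so UMI counts could be recovered, and the recovered totals equalled the deposited UMI counts in all cells. The deposited cell annotation also holds, per the file headers, the number of detected genes, the percent of mitochondrial and of ribosomal UMIs, a cluster number, and for a subsample of 17820 cells (4455 per tissue) the authors' subset name, a total tag count and a cluster from the tags. Values per single tag were not used here, because the annotation gives only their total per cell.

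Each cell was assigned to its library from the deposited annotation and to its tissue and replicate number from the labels. The 17 subset names of the subsample begin with NK, ILC1 or Int, taken here as 3 classes, and every cell of a cluster received the commonest name among its subsampled cells. The class names are the authors'. No doublet caller was run: the tables hold no cell above 4000 detected genes or at 10% mitochondrial UMIs, and no further cell was removed. Total UMIs per library were 29104097, 20514337 and 21355110 in gut, 27043041, 18237548 and 14869307 in liver, 7774017 and 17885868 in salivary gland, and 20976833 and 10703430 in spleen. The tables list 12265 genes in common out of 15231 listed in any, and only the shared genes were tested, since a gene missing from a table has no value there.

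One value per gene and library was computed, the mean over cells of UMIs per 10000, and log2(mean + 0.01) was fitted with limma 3.58.1 in R 4.3.3 (tissue as factor, empirical Bayes with a mean-variance trend, two-sided). Fold changes are on this log2(value + 0.01) scale, which understates the change of low genes. Genes needed a mean of at least 0.02 in at least 2 libraries. P-values were adjusted by the Benjamini-Hochberg method over genes, with a threshold of 0.05. All 10 RNA libraries entered each fit, which left 6 residual degrees of freedom. The count models that fit raw UMI tables were not used as the main test because the deposited unit is a log of scaled values; sums of recovered UMIs were an alternative. Each tissue was compared with the mean of the other 3 over all sorted cells. There the level printed for the other side is the mean of the 3 tissue means, and its SD is over single libraries. The log2 difference averages log values over tissues, so it can exceed the log2 ratio of the printed levels where a tissue is low. Class comparisons used libraries with at least 20 cells of the class: NK class, liver against spleen, and ILC1 class, gut against liver, salivary gland against liver, and gut against salivary gland.

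Gene lists, the comparisons with their tests, and most alternative settings were fixed before the data were examined. A further 6 alternatives and part of the tests of explanations were chosen later, as stated where they are given. There were 26 lists, of which the text names those for NK, mature NK and ILC1 identity, tissue residency, egress and circulation, TGF-beta response, NF-kB targets, immediate early and dissociation stress, cytokines and chemokines, Ly49 and NKG2 receptors, type I interferon response, cytotoxic granules and death ligands, checkpoint receptors and T cells. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 207 tests of a list in a comparison. The estimated-correlation p stands beside each call it ends. The genes named per comparison are the 12 largest rises and 12 largest falls past the threshold whose libraries did not overlap between the sides and whose mean was at least 0.1 per 10000 on the higher side, without predicted, Rik, mitochondrial and ribosomal protein genes. Up to 4 members of each list with the smallest adjusted p are added, and the genes of the sort gate. Genes of the Klra family, Bcl2a1b with Bcl2a1d, Hspa1a with Hspa1b, and Gzmc with its neighbours have near-identical copies, so the split of reads among them is uncertain. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and in R with the data.table package, version 1.17.8. Coordinates are those of GRCm38.p6, the assembly of mm10.

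Simulated data were generated from the real libraries' gene means, residual SDs shuffled over genes, and approximate UMI totals, with up to 200 genes changed. Counting noise was added to SDs that already hold some, so the shares recovered may differ from those of the real tests. Far fewer genes were changed than passed in the real tissue and ILC1 comparisons. The adjusted threshold was therefore stricter in the simulated data, and the shares are not the power of those real tests. The fit recovered 90.7% of 2-fold and 100% of 4-fold changes in the gut comparison, and 26.5% and 79.8% in the NK comparison of liver with spleen. For ILC1 cells the 2-fold and 4-fold shares were 42.0% and 79.6% for gut against liver, 25.3% and 55.0% for salivary gland against liver, and 16.3% and 64.2% for gut against salivary gland. False calls were 7.5% of calls in the simulated liver comparison, above the nominal 5%, and 2.4% to 5.1% in the others. Where shares of cells with a UMI are compared across tissues, each cell was also thinned to 2000 UMIs, which left out shallower cells, 292, 113 and 99 in gut, 144, 705 and 345 in liver, 2 and 47 in salivary gland, and 136 and 66 in spleen. Alternatives were the pseudocount, the filter, the mean of log values, sums of UMIs, median-of-ratios and quantile scaling, other variance models, a 2-fold minimum, thinning, leaving out cells with a UMI of Cd3e, Cd3g, Cd79a, Cd19, Lyz2 or Csf1r, the replicate number as a block, and leaving out each library in turn.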

Results

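Natural killer (NK) cells and type 1 innate lymphoid cells (ILC1) were profiled by droplet single-cell RNA sequencing after one sort, from small-intestinal lamina propria (gut, 3 libraries), liver (3), salivary gland (2) and spleen (2). NK cells are circulating cytotoxic lymphocytes, and ILC1 are related lymphocytes that reside in tissues and share the sorted receptors NKp46 and NK1.1. The libraries held 7465, 4438 and 3755 cells in gut, 5586, 6128 and 4548 in liver, 903 and 3552 in salivary gland, and 5281 and 2781 in spleen. Median UMIs per cell ran from 2850 in the second liver library to 8386 in the first salivary gland library, against 4813 in the second salivary gland library. Libraries of one tissue correlated at r = 0.987 to 0.995 across genes (8 pairs) and libraries of different tissues at 0.838 to 0.978 (37 pairs). Genes are not independent replicates, so these values describe the libraries only. Nothing in the labels says that replicates came from separate animals, so p-values measure the spread between these libraries, which may be technical.

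The transcripts of the sort gate were present in every tissue. Ncr1, which encodes NKp46, stood at 5.66 ± 0.453 UMIs per 10000 in gut (SD, n = 3), 11.96 ± 0.392 in liver (SD, n = 3), 5.29 ± 0.655 in salivary gland (SD, n = 2) and 13.1 ± 0.0550 in spleen (SD, n = 2). Klrb1c, which encodes NK1.1, followed with 4.27 ± 0.339, 9.56 ± 0.543, 5.92 ± 0.420 and 11.6 ± 0.192, and Ptprc, which encodes CD45, with 10.7 ± 1.25, 18.4 ± 1.05, 14.0 ± 0.536 and 20.4 ± 0.273, in the same order. Cd3e, the T cell receptor component excluded by the sort, stayed at 0.00258 ± 0.00337 in gut, 0.0184 ± 0.00808 in liver, 0.00777 ± 0.0110 in salivary gland and 0.0165 ± 0.00918 in spleen. Cd19 was listed in no table, and Adgre1, the F4/80 gene, was listed only for salivary gland, at 0.000534 ± 0.000755. Trbc1, the T cell receptor beta constant gene, stood at 7.87 ± 0.464 in gut, 4.66 ± 1.01 in liver, 3.82 ± 0.314 in salivary gland and 2.87 ± 0.0291 in spleen.

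The mix of cells differed by tissue. Cells with an NK name were 96.8% ± 1.13 of spleen cells (SD, n = 2), 65.2% ± 3.37 of liver cells (SD, n = 3), 33.0% ± 9.38 of salivary gland cells (SD, n = 2) and 8.51% ± 1.26 of gut cells (SD, n = 3). Cells with an ILC1 name were 57.8% ± 1.69 of gut, 40.6% ± 0.0860 of salivary gland, 34.8% ± 3.37 of liver and 3.23% ± 1.13 of spleen. Cells that the authors named Int, read here only as a name, were 33.6% ± 0.945 of gut and 26.4% ± 9.29 of salivary gland, and no cell in liver or spleen carried that name. In 12 exact two-sided permutation tests, over 6 pairs of tissues for the NK and for the ILC1 share, every test gave the smallest p its libraries allow, 0.1, 0.2 or 0.333. With Benjamini-Hochberg adjustment these became 0.24 or 0.333, so no test could pass 0.05, and the Int share was not tested. Among cells above their library's median UMI count the ILC1 share was 46.4% in gut and 44.9% in liver, so depth per cell moved these shares by more than 1 SD. The sort and each cell's depth can set such shares.

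**Figure D1:**
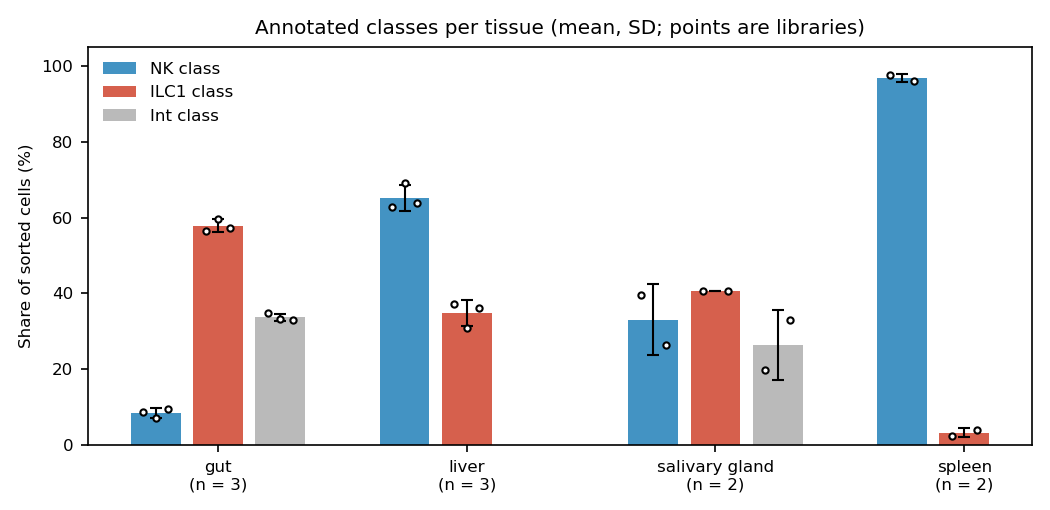
Share of sorted cells in percent (vertical axis) by tissue and annotated class, with bars for means over libraries, error bars for SD and open points for libraries. NK-named cells ran from 8.51% in gut to 96.8% in spleen.

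Within each tissue the ILC1 class carried less of the NK list and more of the ILC1 list than the NK class of the same library. These classes were made from the same expression values, so no test was made. The median NK gene was lower in ILC1 by −3.59 ± 0.135 on the log2 scale in gut (SD, n = 3), −4.47 ± 0.359 in liver (SD, n = 3), −1.43 ± 0.316 in salivary gland (SD, n = 2) and −1.83 ± 0.104 in spleen (SD, n = 2). The median ILC1 gene was higher by 2.34 ± 0.204, 3.43 ± 0.161, 2.41 ± 0.325 and 3.20 ± 0.318 in the same order. Eomes, a T-box factor needed by NK cells, differed by −5.58 ± 0.384 in gut and −5.48 ± 0.320 in liver, and by −1.95 ± 0.209 in salivary gland and −1.32 ± 0.0874 in spleen. Klra4, which encodes the receptor Ly49D, differed by −6.79 ± 0.550 in gut and −7.15 ± 0.198 in liver but by −1.27 ± 0.0607 in salivary gland. Cxcr6, a chemokine receptor of resident lymphocytes, was higher in ILC1 everywhere, by 5.72 ± 0.686 in gut, 7.12 ± 0.336 in liver, 6.81 ± 0.131 in salivary gland and 5.72 ± 0.321 in spleen. Itga1, which encodes CD49a, was higher by 5.60 ± 0.0737 in liver and 2.02 ± 0.134 in gut.

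**Figure D2:**
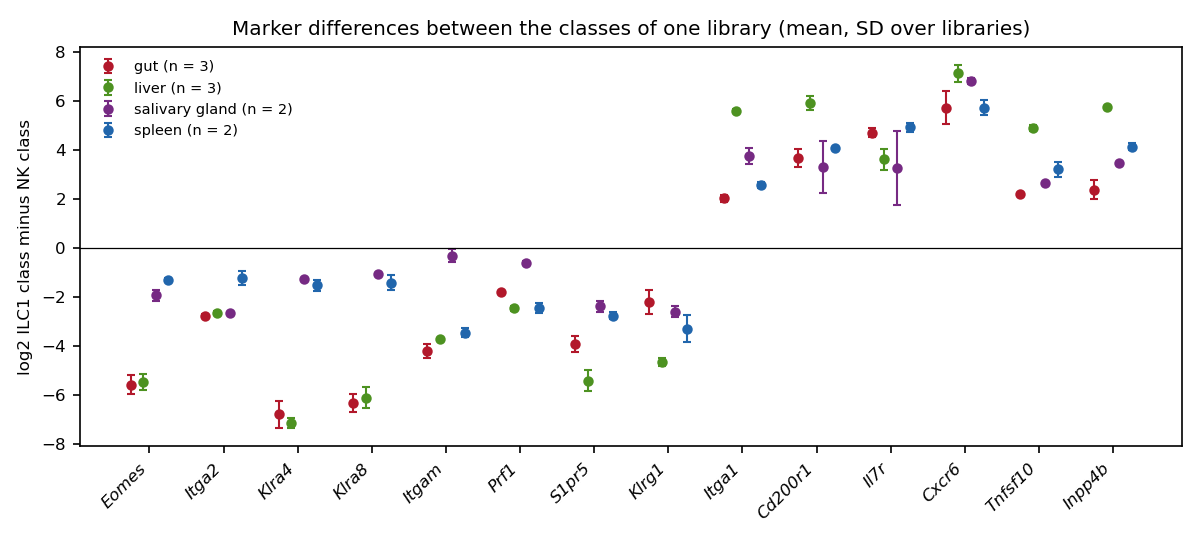
Log2 difference between ILC1-named and NK-named cells of one library (vertical axis) for 14 marker genes, with points for means over libraries and bars for SD, coloured by tissue. Eomes and Klra4 lie nearer 0 in salivary gland (−1.95 and −1.27) and spleen than in gut and liver.

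The first comparison asked what sets gut cells apart from the same sort in the other tissues. Gadd45b, a stress-inducible growth arrest gene, stood at 45.1 ± 1.95 UMIs per 10000 in gut (SD, n = 3). The mean of the other tissues' means was 0.499, with an SD of 0.336 over their libraries (n = 7), a log2 difference of 6.89. Nr4a1, an orphan nuclear receptor induced by antigen-receptor and stress signals, stood at 13.8 ± 1.64 against 0.689 ± 0.935. S1pr5, a sphingosine-1-phosphate receptor used by NK cells to leave tissues, fell by 4.23 on the log2 scale, to 0.0223 ± 0.00685 against 1.17 ± 0.853.

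Among the other largest rises in gut were the protease inhibitor gene Serpinb1a (6.49), the survival genes Bcl2a1d (6.55) and Bcl2a1b (5.61), the lysophospholipid receptor gene Gpr55 (5.50), Gcnt2 (5.43), the hypoxia-inducible lipid droplet gene Hilpda (5.37), Nr4a3 (5.35), Ifitm2 (5.25) and Lilr4b (5.15). Sema4a (−4.19), Ifitm10 (−4.16), Ly6c2 (−4.05), the calcium-binding gene S100a6 (−3.98) and the GTPase gene Rac3 (−3.75) had the largest falls after S1pr5. Gadd45b lies on chromosome 10 at 80930091 to 80932204, Nr4a1 on chromosome 15 at 101253902 to 101274795 and S1pr5 on chromosome 9 at 21242917 to 21248443 (GRCm38.p6). AY036118 also rose by 5.54, but it differed between the gut libraries, at 3.55, 21.6 and 20.4.

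Grouped by list, 13 of 13 NF-kB targets rose in gut, among them Nfkbia (39.2 ± 3.31 against 2.73 ± 1.12) and Nfkbiz (9.23 ± 0.831 against 0.292 ± 0.133). Camera gave an adjusted p of 3.5e-17, and adjusted p = 0.0659 with an estimated correlation. All 19 immediate early and dissociation stress genes rose, with Junb at 71.3 ± 4.60 against 17.05 ± 14.4 and Atf3 at 2.04 ± 0.294 against 0.119 ± 0.157 (camera adjusted p = 1.41e-15, and adjusted p = 0.0773 with an estimated correlation). The other side includes spleen, where all 19 were lower than in the mean of the other tissues. Fos stood at 9.09 ± 1.67 in gut, 8.29 ± 2.48 in liver and 8.23 ± 1.29 in salivary gland. In spleen Fos stood at 0.195 ± 0.0674. Jun was higher in gut, at 20.8, 14.3 and 15.2 in the gut libraries and at most 10.6 in any other. The rise of this list is thus over the mean of the other tissues, not over each tissue for every gene. Each tissue had its own dissociation, so tissue handling cannot be told apart from a biological difference in gut. Of 18 ILC1 genes, 15 rose and 1 fell, led by Rora (4.84), Il2ra (5.03) and the interleukin-7 receptor gene Il7r (5.75 ± 0.962 against 0.327 ± 0.164), with an adjusted p of 2.6e-11. Of 13 cytokine and chemokine genes, 11 rose and 2 fell, with Csf2 (4.35), Ifng (9.57 ± 0.853 against 1.33 ± 0.772) and Xcl1 (49.7 ± 7.56 against 13.6 ± 9.82) at adjusted p = 1.13e-06, and adjusted p = 0.118 with an estimated correlation. Of 20 NK genes, 19 fell, including Zeb2 (0.310 ± 0.00221 against 3.68 ± 2.35), at adjusted p = 6.67e-09, and adjusted p = 0.0734 with an estimated correlation. NK-named cells were 8.51% of gut cells and 33.0% to 96.8% of the other tissues' cells, so this count goes with the mix of cells. ILC1-named cells were 57.8% of gut cells and 3.23% to 40.6% elsewhere, so the ILC1 list count goes with the mix too. Eomes, an example chosen after its values were seen, stood at 0.656 ± 0.0498 in gut and 1.84 ± 0.0603 in liver over all cells, and at 2.32 ± 0.331 and 2.80 ± 0.166 in NK-named cells, a difference not tested. Of 16 Ly49 and NKG2 receptor genes 14 fell and 2 rose (adjusted p = 0.00276, and adjusted p = 0.204 with an estimated correlation). Tissue residency genes (8 rose, 2 fell of 11) and TGF-beta response genes (7 rose, 1 fell of 10) were higher as groups, at adjusted p = 1.03e-05 and 5.24e-05. Egress genes were lower (8 fell, 1 rose of 10, adjusted p = 0.00505, and adjusted p = 0.2 with an estimated correlation). These counts were the same adjusted over the list alone. Among 9 T cell genes 5 rose and 3 fell (adjusted p = 0.029, and adjusted p = 0.25 with an estimated correlation), with Tcrg-C1 at 0.302 ± 0.0536 against 0.0395 ± 0.0383 and Trbc1 at 7.87 ± 0.464 against 3.78 ± 1.00.

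In limma with Benjamini-Hochberg adjustment, 7694 of 10461 genes passed in gut, 2032 higher and 5662 lower, and 2075 differed at least 2-fold. The median of all genes was −0.32, so gut values lie below the rest as a whole. With median-of-ratios scaling 3639 were higher and 3522 lower, and with quantile normalization 3034 and 4163. The named changes exceed this shift many times over, but the 15 interferon-response genes split 5 higher and 9 lower as measured and 6 and 6 with median-of-ratios scaling. Their median was −0.36 while camera pointed up (adjusted p = 0.825). The 13 cytotoxic granule and death ligand genes split 5 higher and 7 lower, or 6 and 6 with median-of-ratios scaling, with a median of −0.44 while camera pointed up (adjusted p = 0.683).

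**Figure D3:**
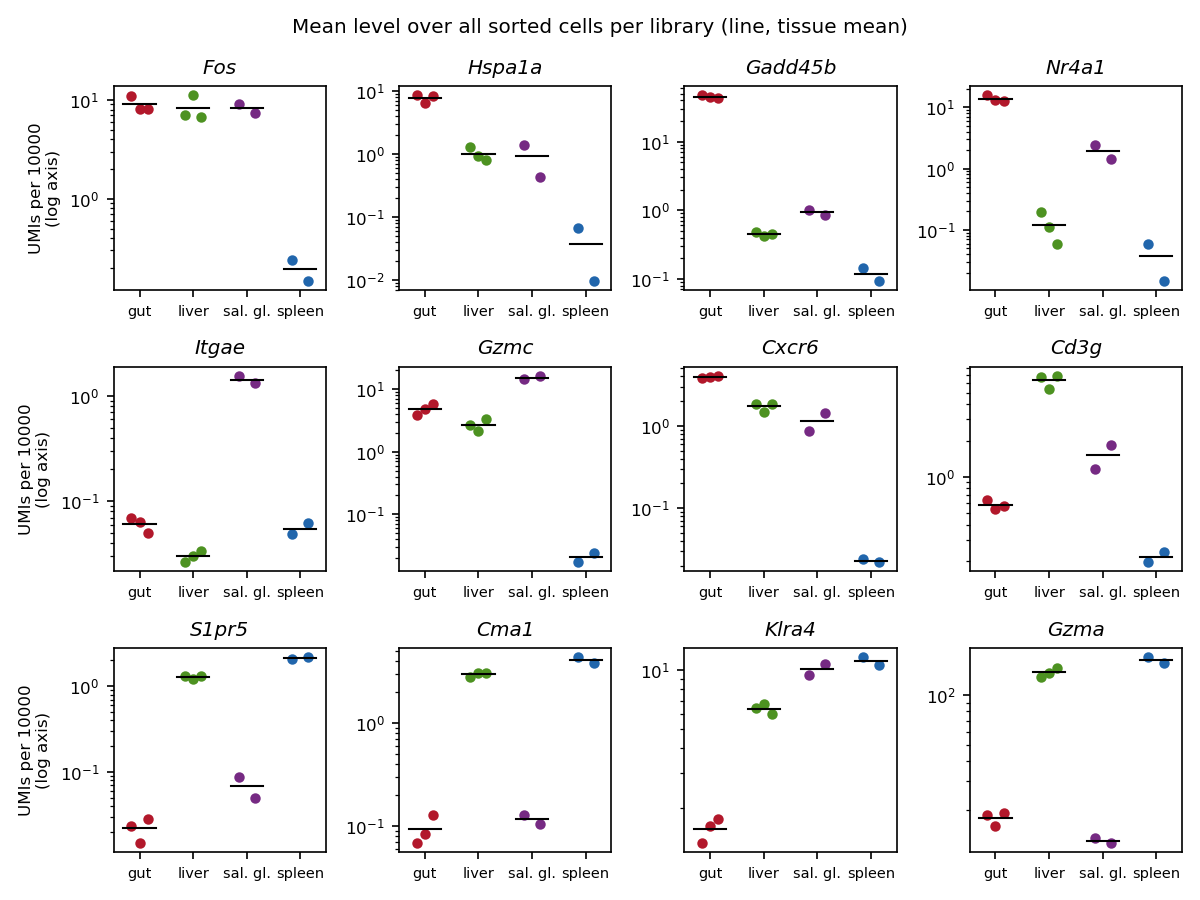
Mean UMIs per 10000 over all sorted cells of a library (vertical axis, log scale) for 12 genes by tissue, with points for libraries and lines for tissue means. Gadd45b averages 45.1 in gut, and Fos averages 0.195 in spleen.

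The liver comparison asked what sets liver cells apart. Liver cells held more Cd3g, which encodes the CD3 gamma chain, at 6.36 ± 0.821 UMIs per 10000 (SD, n = 3) against 0.769 ± 0.584 elsewhere (SD, n = 7), a log2 difference of 3.44. The CD200 receptor family genes Cd200r2 (3.27) and Cd200r1 (2.37), the lipid flippase gene Atp8a2 (3.43), the metalloprotease gene Adam19 (3.09) and the Ly49 gene Klra5 (1.07 ± 0.103 against 0.157 ± 0.0301) were higher too. Cd200r1 in gut was near its liver level, at 0.473, 0.416 and 0.325 in the gut libraries against 0.518, 0.503 and 0.516 in liver. Itgae, the integrin CD103, was lower at 0.0300 ± 0.00356 against 0.514 ± 0.670, where salivary gland alone stood at 1.43 ± 0.152, gut at 0.0604 ± 0.00970 and spleen at 0.0550 ± 0.00922. The chemokine receptor gene Cxcr4 fell by 2.17 on the log2 scale. Ccdc136 (2.98), Htra3 (2.51), Cd63 (2.45), Nav2 (2.12), Il2 (1.82) and Olfr1259 (1.81) completed the largest rises. Cd74 (−1.36), Sdc4 (−1.04), Tcf7 (−0.98), Ubald2 (−0.90), Crtam (−0.78), Tmem156 (−0.70), Cd28 (−0.70), Kbtbd11 (−0.67), Gpr18 (−0.66) and Malt1 (−0.63) were the remaining falls. Klra5 was no longer past the threshold and Htra3 turned to −0.23 without cells holding a UMI of Cd3e, Cd3g, Cd79a, Cd19, Lyz2 or Csf1r, a filter that takes out 21.9% to 29.4% of liver cells.

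All 13 NF-kB targets fell in liver, with Nfkbia at 2.24 ± 0.107 against 15.1 ± 19.5 and Rel at 0.393 ± 0.0117 against 2.33 ± 2.88 (camera adjusted p = 9.49e-22). The other side includes gut, where these genes were highest. Of 10 TGF-beta response genes 7 fell and 1 rose, led by Tgif1 (−2.09) and Pmepa1 (−2.38), at adjusted p = 2.75e-11. All 12 mature NK genes rose (adjusted p = 5.88e-13), and 16 of 20 NK genes rose (17 adjusted over the list alone), with the granzyme gene Gzma at 138 ± 9.05 against 65.1 ± 72.4 and the chymase gene Cma1 at 3.00 ± 0.135 against 1.44 ± 1.96. The NK list had an adjusted p of 5.81e-12, and adjusted p = 0.0644 with an estimated correlation. The spleen libraries stood higher than liver in Gzma, at 171 and 158, and in Cma1, at 4.38 and 3.83. Gzmb of the mature NK list went the other way, at 6.98 and 6.36 in spleen and 21.0, 18.8 and 18.3 in liver. Rises of these lists thus set liver apart from the mean of the other tissues, not from each tissue. Egress genes rose in 9 of 10 and fell in 1, with Klf2 at 17.9 ± 2.01 against 8.12 ± 7.04 (adjusted p = 8.33e-07, and adjusted p = 0.0691 with an estimated correlation). ILC1 genes went both ways, 7 up and 6 down of 18, or 7 and 7 with median-of-ratios scaling, and 14 passed adjusted over the list alone. Their median was 0.14 while camera pointed down (adjusted p = 0.743). Other counts were the same adjusted over the list alone.

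By limma with Benjamini-Hochberg adjustment, 4572 of 10461 genes passed in liver, 3599 higher and 973 lower, and 368 differed at least 2-fold. The median of all genes was 0.19, and with median-of-ratios scaling 1469 genes were higher and 1759 lower, with quantile normalization 1798 and 1496. Without the third liver library 2992 passed, and with the mean of log values 2049, of which 763 were higher and 1286 lower. NK-named cells were 65.2% of liver cells, against 8.51% in gut and 96.8% in spleen, and the list counts above are over this mix.

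The salivary gland comparison asked what sets these cells apart. Salivary gland cells held more Itgae (1.43 ± 0.152, SD, n = 2, against 0.0485 ± 0.0161, SD, n = 8, a log2 difference of 4.66) and more Gzmc (15.3 ± 1.03 against 2.51 ± 2.07), a granzyme gene. They held less Gzma (13.1 ± 0.664 against 107 ± 68.7) and less Il7r (0.163 ± 0.00547 against 2.19 ± 2.80). Gzma in the gut libraries was nearer, at 18.6, 16.1 and 19.1. Il7r was highest in gut, at 6.22, 6.39 and 4.64, with 0.431, 0.496 and 0.584 in liver and 0.256 and 0.370 in spleen. The tyrosine kinase gene Matk (5.25) and the muscle-type genes Tnni1 (4.97) and Cox6a2 (4.73) led the rises, followed by Gsta4 (4.45), Chl1 (4.37), Sema6d (3.97), Osbpl1a (3.71), Apol9b (3.66), Zfp839 (3.55) and Ramp1 (3.53). Klf3 (−3.50), Atp8a2 (−3.15), the GTPase regulators Rasgrp2 (−3.02) and Rap1gap2 (−2.71), Gpr55 (−2.98), Arl5c (−2.76), Pde5a (−2.75), Xdh (−2.68), Acoxl (−2.39) and Angpt1 (−2.32) fell.

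Of 10 TGF-beta response genes 8 rose and 1 fell in salivary gland, with Ldlrad4 (0.917 ± 0.0153 against 0.130 ± 0.109) and Pmepa1 (3.09) beside Itgae, while the ectonucleotidase gene Entpd1 fell by 2.11 (camera adjusted p = 3.08e-05). Of 10 egress genes 9 fell, including Cx3cr1 (−2.67), S1pr5 (−2.54) and S1pr1 (−2.39), at adjusted p = 7.25e-09, and adjusted p = 0.058 with an estimated correlation. Residency genes split 8 up and 3 down of 11, with Itga1 (2.17) and Rgs2 (1.60) up and Prdm1 (−2.05) down, at adjusted p = 0.0025, and adjusted p = 0.0773 with an estimated correlation. Of 20 NK genes 13 fell and 6 rose, with Klrg1 at 0.146 ± 0.0336 against 1.25 ± 0.873 (adjusted p = 0.000242, and adjusted p = 0.19 with an estimated correlation). ILC1 genes rose in 11 of 18 and fell in 4, led by the phosphatase gene Inpp4b (1.72 ± 0.126 against 0.381 ± 0.247), at adjusted p = 0.00691, and adjusted p = 0.232 with an estimated correlation. These counts were the same adjusted over the list alone. In limma with Benjamini-Hochberg adjustment, 4023 of 10461 genes passed, 1994 higher and 2029 lower, and 717 differed at least 2-fold. With the mean of log values 3518 were higher and 989 lower, so the balance of directions depends on the scale. NK-named cells were 33.0% of salivary gland cells and ILC1-named cells 40.6%, and the list counts above are over this mix.

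The spleen comparison asked what sets spleen cells apart. Spleen cells held more S1pr5 (2.14 ± 0.0499, SD, n = 2, against 0.460 ± 0.647, SD, n = 8, a log2 difference of 3.87), Cma1 (4.11 ± 0.387 against 1.07 ± 1.502) and the migration receptor gene S1pr1 (0.545 ± 0.0560 against 0.0832 ± 0.104). They held far less Gzmc (0.0207 ± 0.00494 against 7.62 ± 5.50), Cxcr6 (0.0231 ± 0.00140 against 2.27 ± 1.29) and Fos (0.195 ± 0.0674 against 8.54 ± 1.72), an AP-1 transcription factor gene induced within minutes of stimulation. Ly6c2 (3.55), Cym (3.38), the fractalkine receptor gene Cx3cr1 (3.17), Rac3 (2.83), G0s2 (2.73), Zeb2os (2.68), Klrg1 (2.68), Rap1gap2 (2.66) and Elovl7 (2.66) were the other rises. In the liver libraries S1pr5 was nearer its spleen level, at 1.33, 1.21 and 1.33, while no gut or salivary gland library exceeded 0.0884. Dusp1 (−5.76), Hspa1a (−5.57), Ier5l (−5.51), Maff (−4.99), Osgin1 (−4.89), Nr4a2 (−4.60), Rgs1 (−4.50), Gadd45b (−4.41) and Fosb (−4.33) were the other falls.

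All 19 immediate early and dissociation stress genes fell in spleen, with Junb at 2.68 ± 0.148 against 39.9 ± 27.7 (camera adjusted p = 2.18e-21, and adjusted p = 0.0659 with an estimated correlation). All 18 ILC1 genes fell, led by Cxcr6, Inpp4b (−4.30) and Itga1 (−4.20), at adjusted p = 6.58e-22. ILC1-named cells were 3.23% of spleen cells and 34.8% to 57.8% of the other tissues' cells, so the ILC1 list count goes with the mix of cells. Within ILC1-named cells Cxcr6 stood at 0.676 ± 0.233 in spleen, 6.05 ± 0.320 in gut, 4.95 ± 0.173 in liver and 2.39 ± 0.745 in salivary gland, and no test of spleen against these levels is given. Residency genes fell in 10 of 11 and rose in 1, at adjusted p = 2.57e-12. Of 20 NK genes 19 rose, among them Zeb2 (6.22 ± 1.43 against 1.72 ± 1.90) and Gzma (164 ± 9.12 against 56.3 ± 63.3), at adjusted p = 3.96e-14. NK-named cells were 96.8% of spleen cells and 8.51% to 65.2% elsewhere, so the NK list count goes with the mix too. TGF-beta response genes (8 fell, 1 rose of 10, adjusted p = 5.19e-07) and checkpoint and costimulation genes (9 fell, 1 rose of 10, adjusted p = 1.18e-06) were lower. All 13 NF-kB targets fell (adjusted p = 2.01e-15, and adjusted p = 0.0691 with an estimated correlation), as did 12 of 13 cytokine and chemokine genes, with 1 higher, such as Xcl1 (2.38 ± 0.567 against 29.3 ± 18.0), at adjusted p = 2.58e-10, and adjusted p = 0.0691 with an estimated correlation. Egress genes rose in 9 of 10, and 10 passed adjusted over the list alone (adjusted p = 1.05e-06, and adjusted p = 0.0691 with an estimated correlation). Other counts to this point were the same adjusted over the list alone. Among 9 T cell genes 6 fell and 1 rose, and 8 passed adjusted over the list alone, with Cd3g at 0.216 ± 0.0299 against 2.82 ± 2.86 (adjusted p = 0.00379, and adjusted p = 0.173 with an estimated correlation).

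By limma with Benjamini-Hochberg adjustment, 5089 of 10461 genes passed in spleen, 3254 higher and 1835 lower, and 1012 differed at least 2-fold. The median of all genes was 0.14, and with median-of-ratios scaling 2280 were higher and 2655 lower. With the mean of log values 1893 were higher and 1948 lower. Without the second spleen library 3284 passed.

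**Figure D4:**
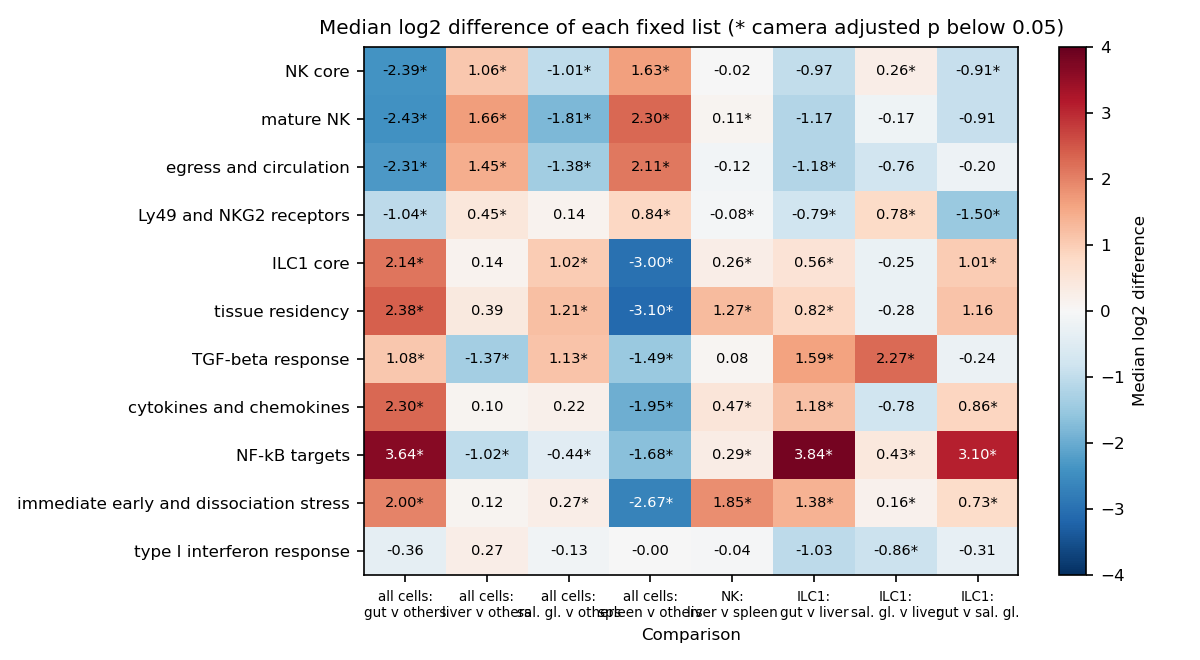
Median log2 difference of the tested members of 11 fixed gene lists (vertical axis) in 8 comparisons (horizontal axis), as numbers and colour, with asterisks where camera gave an adjusted p under 0.05. NF-kB targets have medians of 3.64 in gut, −1.02 in liver and −1.68 in spleen. Asterisks use the preset correlation. Over all lists 99 calls passed with it and 20 with an estimated correlation, under which the gut and spleen NF-kB calls were lost.

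Restricting the comparison to NK-named cells asked whether circulating-type cells differ between liver and spleen. Of the 80 genes past the threshold 17 belong to the immediate early and stress list, and 60 passed when that list was left out, an alternative chosen after seeing the data. Fos stood at 9.99 ± 2.64 UMIs per 10000 in liver NK cells (SD, n = 3) against 0.197 ± 0.0680 in spleen NK cells (SD, n = 2), a log2 difference of 5.60. Dusp1, a MAP kinase phosphatase gene, stood at 2.89 ± 0.715 against 0.0880 ± 0.0238, and Jun at 8.75 ± 1.26 against 1.46 ± 0.186. Fosb (4.24), Emp1 (3.34), Nr4a2 (3.23), Klf4 (3.19), Sik1 (3.03), Rgs1 (2.89), Ppp1r15a (2.53), Hspa1a (4.72) and Hspa1b (3.50) were also higher in liver, and Madd (−0.79) was lower at an adjusted p of 0.0285. Madd had an adjusted p of 0.0727 to 0.63 without each liver or spleen library in turn. Of 19 immediate early and stress genes 17 rose, and 18 passed adjusted over the list alone (camera adjusted p = 1.81e-96). The 2 tissues were dissociated separately, so tissue handling cannot be told apart from a biological difference here. Residency genes rose in 4 of 10 (6 adjusted over the list alone, adjusted p = 1.11e-18), namely Rgs1, Cd69 (2.46 ± 0.535 against 0.477 ± 0.0759), Rgs2 (1.62 ± 0.296 against 0.439 ± 0.0225) and Nr4a1. Nr4a1 is a member of the immediate early and stress list too, and the limit on handling holds for the residency genes as well. The Nr4a1 call stood only without the third liver or the first spleen library, and leaving out any other library gave an adjusted p of 0.0526 to 0.73. Cytokine genes rose in 3 of 11 (5 adjusted over the list alone), namely Ifng (2.36 ± 0.431 against 0.725 ± 0.151), Ccl3 (2.34) and Ccl4 (2.38), at adjusted p = 3.85e-09, and adjusted p = 0.0734 with an estimated correlation. NK genes passed in 1 of 20 (3 adjusted over the list alone), the interferon regulatory factor gene Irf8 (7.01 ± 0.227 against 3.80 ± 0.0855). Of 12 mature NK genes 1 rose (2 adjusted over the list alone, camera adjusted p = 0.0321, and adjusted p = 0.235 with an estimated correlation), a call lost without the third liver library (0.0758) or the second spleen library (0.198) and with the replicate block (0.404). Of 16 Ly49 and NKG2 receptor genes 0 passed, while camera pointed down (adjusted p = 0.0483, and adjusted p = 0.235 with an estimated correlation). That call was lost without any 1 of the gut libraries (0.0555, 0.0745 and 0.0728), the third liver library (0.18) or the first spleen library (0.713), and with the replicate block (0.074).

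In limma with Benjamini-Hochberg adjustment, 80 of 10279 genes passed in NK cells, 77 higher in liver and 3 lower, while 435 had an unadjusted p under 0.05. Without the second spleen library 48 passed, without a variance trend 53, and with the mean of log values 33, of which 17 were higher and 16 lower. With the mean of log values Hspa1a, Hspa1b, Nr4a2, Klf4, Sik1, Ppp1r15a, Ifng, Ccl3, Irf8 and Nr4a1 were no longer past the threshold. In simulated data 26.5% of 2-fold changes were recovered in this comparison, so a gene not past the threshold is not shown to be equal.

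Among ILC1-named cells the comparisons asked how one class differs between tissues. The gut class holds the subset ILC1_LPL2, 26.1% ± 0.290 of gut ILC1 (SD, n = 3), whose 10 leading genes include the ILC3 markers Il22 and Rorc and no ILC1 marker of the fixed set. The liver class holds ILC1_Liv1, 79.3% ± 3.63 of liver ILC1, whose 10 leading genes include the T cell marker Cd3g and no ILC1 marker of that set. The lack of an ILC1 marker is not particular to them, since the other gut subset, ILC1_LPL1, has none among its 10 either. Because of the ILC3 and T cell markers, counts without both subsets, chosen after seeing the data, are given beside the main ones.

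Gut ILC1 cells held more Nr4a1 (15.1 ± 2.19, SD, n = 3, against 0.0513 ± 0.0252 in liver ILC1, SD, n = 3, a log2 difference of 8.04), Gadd45b (57.5 ± 3.26 against 0.718 ± 0.0334) and Crem (11.7 ± 1.52 against 0.132 ± 0.00355), a cAMP-responsive factor gene. They held less S100a6 (0.367 ± 0.0574 against 25.8 ± 2.23), Cd3g (0.321 ± 0.0560 against 17.9 ± 0.786) and Cd7 (1.92 ± 0.226 against 31.9 ± 6.04). Atf3 (7.002), the hexokinase gene Hk2 (6.58), Cdkn1a (6.42), Serpinb1a (6.27), Hilpda (6.21), the RANK ligand gene Tnfsf11 (6.21), Nr4a3 (6.14), Rasl11a (5.83) and Tgif1 (5.74) were the other large rises. Sema4a (−5.03), BC147527 (−4.87), Ifitm10 (−4.68), S100a4 (−4.54), Kcnj8 (−4.22), Nav2 (−4.13), Tspan15 (−4.11) and Pdgfb (−4.05) fell. Htra3 (−4.87) also fell, but its adjusted p was 0.175 without the subsets ILC1_LPL2 and ILC1_Liv1.

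All 13 NF-kB targets rose in gut ILC1, with Nfkbia at 42.9 ± 3.92 against 2.22 ± 0.371 (camera adjusted p = 4.52e-23). TGF-beta response genes rose in 7 of 10 and fell in 1, led by Tgif1 and Skil (3.53 ± 0.272 against 0.471 ± 0.0391), at adjusted p = 5.82e-06. Immediate early and stress genes rose in 13 of 19 (adjusted p = 1.99e-12, and adjusted p = 0.0659 with an estimated correlation). Tissue handling cannot be told apart from a biological difference here either. ILC1 genes split 9 up and 7 down of 18, with Rora (8.97 ± 0.408 against 0.391 ± 0.0651) and Il2ra (4.57) up and Itga1 (0.860 ± 0.153 against 4.27 ± 0.254) down (adjusted p = 0.00809, and adjusted p = 0.28 with an estimated correlation). Ly49 and NKG2 genes fell in 11 of 16 and rose in 1, with Klra9 at −3.85 (adjusted p = 0.0157, and adjusted p = 0.2 with an estimated correlation). These counts were the same adjusted over the list alone. By limma with Benjamini-Hochberg adjustment, 6024 of 10577 genes passed, 1368 higher and 4656 lower, and 2553 differed at least 2-fold. Without both subsets 4996 passed, of which 4497 were among these. The median of all genes was −0.40, and with median-of-ratios scaling 2628 were higher and 2240 lower, with quantile normalization 2034 and 2821.

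Salivary gland ILC1 cells held more Itgae (2.90 ± 0.492, SD, n = 2, against 0.00879 ± 0.00157 in liver ILC1, SD, n = 3, a log2 difference of 7.27), the NK receptor genes Klra4 (6.38 ± 0.763 against 0.0588 ± 0.00798) and Klra8 (5.76 ± 0.937 against 0.119 ± 0.0511), and Eomes (0.881 ± 0.123 against 0.0535 ± 0.0123). They held less Gzma (5.17 ± 1.85 against 87.2 ± 7.41), Cd200r1 (0.153 ± 0.0795 against 1.46 ± 0.127) and Cxcr3 (0.628 ± 0.175 against 3.63 ± 0.361), a chemokine receptor gene. Tnni1 (6.94), the growth factor gene Vegfa (6.73), Matk (6.498), Cox6a2 (5.33), Abcb1b (5.29), Ier5l (5.17), Ccdc88a (5.09) and Klra1 (5.06) rose as well, and Gsta4, listed at 0 in all liver ILC1 libraries, stood at 0.426 ± 0.0172. Atp8a2 (−6.44), Cd200r2 (−4.66), Acoxl (−4.42), Pdzd2 (−4.26), Tspan15 (−4.22), Tesc (−4.01), Cd63 (−3.89), Abca3 (−3.67), Ifit1bl1 (−3.63) and Rasgrp2 (−3.61) fell. Klra5 (−3.58) and Cd3g (2.55 ± 0.569 against 17.9 ± 0.786) fell too, with adjusted p of 0.175 for both without the subsets ILC1_LPL2 and ILC1_Liv1. Klra5 turned to 0.0852 without cells holding a UMI of Cd3e, Cd3g, Cd79a, Cd19, Lyz2 or Csf1r.

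Of 10 TGF-beta response genes 8 rose and 1 fell, with Ldlrad4 at 1.47 ± 0.110 against 0.0588 ± 0.0106 and Smad7 at 3.62 ± 0.275 against 0.898 ± 0.108 (camera adjusted p = 7.1e-09). Of 16 Ly49 and NKG2 receptor genes 9 rose and 7 fell (adjusted p = 0.0298, and adjusted p = 0.227 with an estimated correlation), a call lost without the second salivary gland library at 0.106. Of 20 NK genes 10 rose and 5 fell, and 18 passed adjusted over the list alone (adjusted p = 0.00063, and adjusted p = 0.2 with an estimated correlation). Interferon-response genes fell in 10 of 15 and rose in 1 (12 adjusted over the list alone), with Zbp1 at 0.310 ± 0.0190 against 0.749 ± 0.0253 and Isg20 higher at 1.15 ± 0.141 against 0.213 ± 0.0434 (adjusted p = 0.00269, and adjusted p = 0.204 with an estimated correlation). In limma with Benjamini-Hochberg adjustment, 2612 of 10577 genes passed, 912 higher and 1700 lower, and 1152 differed at least 2-fold. The median of all genes was −0.16, and with median-of-ratios scaling 1352 were higher and 1134 lower, with quantile normalization 1221 and 1338, and with the mean of log values 1653 and 729. The count was 1421 without the first salivary gland library, 4037 or 4019 without the first or second spleen library, 1553 with cells thinned to 2000 UMIs, 1475 with only subsampled cells, and 1879 without both subsets, of which 1557 were among the 2612.

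Gut ILC1 cells, set directly against salivary gland ILC1, held more Serpinb1a (3.39 ± 0.175, SD, n = 3, against 0.0167 ± 0.00185, SD, n = 2, a log2 difference of 6.99), Csf2 (1.86 ± 0.527 against 0.0301 ± 0.00553), which encodes GM-CSF, and Il7r (8.60 ± 1.31 against 0.362 ± 0.0280). They held less Itgae (0.0236 ± 0.00676 against 2.90 ± 0.492), Klra4 (0.0446 ± 0.0179 against 6.38 ± 0.763) and Klra7 (0.0945 ± 0.0151 against 4.97 ± 0.267). Gpr55 (6.70), Plac8 (6.498), Bcl2a1d (6.18), Gadd45b (6.09), Ifitm2 (6.09), the hypoxia-responsive factor gene Epas1 (6.01), Gcnt2 (5.90), Bcl2a1b (5.84) and Rasl11a (5.61) rose, as did AY036118 (5.92), which varied between gut libraries. Tnni1 (−7.33), Cox6a2 (−6.72), Klra8 (−6.52), Sema4a (−5.96), S100a6 (−5.94), Gprin3 (−5.87), Matk (−5.70), Klra1 (−5.57) and Gsta4 (−5.28) fell.

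All 13 NF-kB targets rose in this contrast, with Nfkbiz at 10.5 ± 1.06 against 0.273 ± 0.00933 (camera adjusted p = 3.7e-19). Cytokine and chemokine genes rose in 9 of 13 and fell in 3, with Ifng at 8.98 ± 0.621 against 0.750 ± 0.0658 and Ccl3 at 15.1 ± 4.42 against 2.10 ± 0.572 (adjusted p = 0.000824, and adjusted p = 0.153 with an estimated correlation). Ly49 and NKG2 receptor genes fell in 11 of 16 and rose in 4 (adjusted p = 0.00557, and adjusted p = 0.161 with an estimated correlation). NK genes fell in 11 of 20 and rose in 3, and 15 passed adjusted over the list alone (adjusted p = 0.00191, and adjusted p = 0.225 with an estimated correlation). ILC1 genes rose in 10 of 18 and fell in 6 (adjusted p = 0.0122, and adjusted p = 0.314 with an estimated correlation), while TGF-beta response genes split 2 up and 3 down of 10, or 3 up and 2 down with median-of-ratios scaling (adjusted p = 0.844). Other counts were the same adjusted over the list alone. By limma with Benjamini-Hochberg adjustment, 4951 of 10577 genes passed, 1615 higher and 3336 lower, and 2255 differed at least 2-fold. Without both subsets 4283 passed, of which 4171 were among these. The median of all genes was −0.25, and with median-of-ratios scaling 2568 were higher and 2150 lower, with quantile normalization 2152 and 2543, and with the mean of log values 1096 and 4186.

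The tag libraries entered only as totals per cell and as the authors' clusters. Median tag counts per cell were 65 to 90 in the gut libraries, 100 to 244 in liver, 357 and 1918 in salivary gland, and 329 and 475 in spleen. Of the 7 clusters that the authors made from the tags, 3 held mostly NK-named cells at 95.2%, 98.7% and 91.6%, and 1 held 91.0% ILC1-named cells. The others were mixed, with 67.9% and 60.1% ILC1-named and 65.9% NK-named cells. Spleen ILC1-named cells fell largely in the 3 NK clusters, at 42.6% ± 6.67, 2.49% ± 1.62 and 13.6% ± 3.75 (SD, n = 2). Only 5.90% ± 4.52 of them fell in the cluster with 91.0% ILC1-named cells, and 21.9% ± 5.30 in that with 60.1%.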

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

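The tests of immediate early genes and of T cells in liver ILC1, and the other splits of the libraries, were chosen after the results were seen. The test of a gene overlapping Cd3g and both tests of Cd74 were chosen before.

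The difference between ILC1-named and NK-named cells of a library itself differed between tissues for many marker genes, in a limma interaction test with Benjamini-Hochberg adjustment over 10064 genes. Of 14 marker genes, 8 passed for gut against liver, 11 for salivary gland against liver, 8 for gut against salivary gland and 10 for spleen against liver. Classes were made from the same expression values, so these values describe the named classes. The ILC1 class here includes ILC1_LPL2, 26.1% of gut ILC1 with the ILC3 markers Il22 and Rorc among its 10 leading genes, and ILC1_Liv1, 79.3% of liver ILC1 with the T cell marker Cd3g among its 10. Neither has an ILC1 marker of the fixed set among them, but nor does the other gut subset, ILC1_LPL1. These differences were not computed without both subsets. For gut minus liver the log2 values were Cd200r1 −2.24, Cxcr6 −1.40, Inpp4b −3.37, Itga1 −3.58, Klrg1 2.46, Prf1 0.65, S1pr5 1.499 and Tnfsf10 −2.69. For salivary gland minus liver they were Cd200r1 −2.61, Eomes 3.54, Inpp4b −2.30, Itga1 −1.86, Itgam 3.39, Klra4 5.88, Klra8 5.05, Klrg1 2.05, Prf1 1.86, S1pr5 3.05 and Tnfsf10 −2.26. For gut minus salivary gland they were Eomes −3.63, Inpp4b −1.07, Itga1 −1.72, Itgam −3.89, Klra4 −5.52, Klra8 −5.27, Prf1 −1.21 and S1pr5 −1.55. For spleen minus liver they were Cd200r1 −1.85, Eomes 4.17, Inpp4b −1.63, Itga1 −3.04, Itga2 1.45, Klra4 5.62, Klra8 4.70, Klrg1 1.36, S1pr5 2.67 and Tnfsf10 −1.70.

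Genes of the fixed lists that are missing from at least 1 tissue's table, and so were not tested, had RNA above the floor of 0.1 UMIs per 10000 in some tissues. The interleukin-22 gene Il22 stood at 1.87 in gut, the amphiregulin gene Areg at 1.496, Ctla4 at 0.634, Ccl1 at 0.228 and Rorc, which encodes the ILC3 factor RORgt, at 0.196. Ctla4 stood at 0.194 in salivary gland. The immunoglobulin genes Igha in salivary gland, Igkc in gut and Igkc in spleen stood at 0.341, 0.198 and 0.101.

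Immediate early and stress genes were lower in spleen than in the mean of the other tissues. Depth per cell is argued against, since the median difference of the list was −2.68 with every cell thinned to 2000 UMIs. Tissue handling that acts on every cell may contribute, since the list was lower in both classes, with medians of −2.49 in NK-named and −2.20 in ILC1-named cells. Handling cannot be told apart from a biological difference between tissues, because each tissue had its own dissociation. The cause of the difference between tissues stays open.

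Cd3g RNA was high in liver ILC1, with a UMI in 70.8%, 63.1% and 70.4% of ILC1-named cells against 4.74%, 3.33% and 4.37% of NK-named cells, at median depths of 4907.5, 3188 and 3452.5 against 4426, 2675 and 2914.5 UMIs. T cells or T cell doublets as the source of most Cd3g RNA are argued against by Cd3e, since at most 1.15% of ILC1 cells with a Cd3g UMI held a Cd3e UMI, and the sort removed cells with surface CD3, but a smaller share of T cells stays open: 0.817%, 0.686% and 0.426% of ILC1 cells against 0.0285%, 0.0236% and 0% of NK cells held a Cd3e UMI, and the T cell list was higher in ILC1 by a median of 1.49 ± 0.152, with 4 of 6 members higher in every library. An earlier test left out cells with a UMI of Cd3e, Trac, Trbc1, Trbc2 or Cd3d and kept as little as 48.3% of the Cd3g level in 1 library, which met the bound set for T cells in that library, but Trbc1 was in most cells and only 26, 74 and 54 cells were left, so it decides nothing. Reads of an overlapping gene are argued against, as 0 annotated genes overlap Cd3g (chromosome 9, 44969572 to 44980431), and Cd3d lies 1337 bases away. Cd3g differed by −5.77 in gut against liver ILC1 (limma, Benjamini-Hochberg adjusted p = 3e-11), and its biological cause was not tested.

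Cd74, the invariant chain gene of MHC class II, was high in spleen ILC1. Without cells holding a UMI of Cd79a, Cd79b, Ms4a1, Ighm, Igkc or Ighd, Cd74 was 58.5 and 489 times its level in the spleen NK class in the 2 libraries, which argues against B cells as the whole source, though only 39 and 32 of 128 and 112 cells were left. Leaving those cells out took Cd74 from 3.15 to 1.34 UMIs per 10000 in the first library and from 6.93 to 5.16 in the second. The NK-class levels were only 0.0228 and 0.0105, so the size of the ratios is uncertain. A B cell UMI was present in 69.5% and 71.4% of ILC1 cells and in 27.5% and 28.8% of NK cells. Without cells holding a UMI of Lyz2, Zbtb46 or Itgax the ratios were 164 and 876 with 80 and 75 cells left, but only 3 of the 10 myeloid and dendritic genes are listed, so such cells cannot be told apart from ILC1 as a possible source, although the sort kept NKp46- and NK1.1-positive cells and gated out a macrophage marker.

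Of 100 splits of the libraries, 1 gave as many genes as the gut comparison, the real one with 7694, and the highest other gave 801. Other splits mostly mix tissues within a label, and their median was 0 genes. Libraries of one tissue are alike, so such splits could hardly give many genes, and this count does not exclude chance. For liver 2 of 100 splits gave at least the real 4572, and the highest other, 6130, arose where the 3 gut libraries took the label, which points to a structure of the samples. Of the 10 splits of gut and liver ILC1, 1 gave as many as the real 6024 and the highest other gave 0. These are too few splits for a share under 0.05.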

How the results depend on the processing

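These 6 alternatives were chosen after seeing the data: genes absent from a table set to 0, only subsampled cells, the class without ILC1_LPL2, the class without ILC1_LPL2 and ILC1_Liv1, tests without the immediate early list, and lists with at least 3 tested members. Over 543 gene results there were 15014 values under alternatives, of which 14889 kept direction and side of the threshold, 110 kept direction only, and 15 reversed. Many of these genes were named as the largest changes, so their stability follows in part from that choice. The 2-fold minimum acts only on the counts of genes, so its 543 gene values could not differ from the main fit. These values are among the 14889 and say nothing on stability. Where no cause is named below, the cause was not tested.

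With a minimum of 2-fold the counts were 2075 in gut, 368 in liver, 717 in salivary gland, 1012 in spleen, 2553 for ILC1 in gut against liver, 1152 in salivary gland against liver and 2255 in gut against salivary gland, lower by construction. With the mean of log values the liver count was 2049 and that of NK cells 33, and without a variance trend that of NK cells was 53. For ILC1 in salivary gland against liver the count was 1553 with thinned cells and 1475 with subsampled cells, which leaves fewer cells. Leaving out each library in turn gave 7004 to 7700 in gut, 2992 (without the third liver library) to 5224 in liver, 2921 to 4213 in salivary gland, 3284 (without the second spleen library) to 5501 in spleen, and 48 (without the second spleen library) to 91 in NK cells. For ILC1 it gave 4869 to 7093 in gut against liver, 1421 to 4037 in salivary gland against liver and 3457 to 6151 in gut against salivary gland. A lone library left in a tissue is assumed to vary like the others. Without ILC1_LPL2 the ILC1 counts were 6062, 2510 and 4984.

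Of 207 list tests 99 passed with the preset correlation and 20 with an estimated correlation. Fry gave 152 calls, 93 of them shared with camera. Fry tests whether a set's genes move one way and compares nothing with other genes. With lists of at least 3 tested members 91 passed.

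Among cells above the median UMI count of their library, ILC1 were 46.4% and Int 44.3% of gut cells, NK 55.1% and ILC1 44.9% of liver cells, ILC1 42.9% of salivary gland cells, and NK 94.3% and ILC1 5.66% of spleen cells.

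Without cells holding a UMI of Cd3e, Cd3g, Cd79a, Cd19, Lyz2 or Csf1r, a filter that removes most liver ILC1 through Cd3g, the liver comparison gave Htra3 −0.23, Itga1 −0.081 and Tnfsf10 −0.26, and ILC1 in salivary gland against liver gave Cd28 −0.28, Emb −0.10 and Klra5 0.0852. With the mean of log values Tcrg-C1 in liver was −0.023. Without ILC1_LPL2 and ILC1_Liv1, gut against liver gave Gpr183 −0.55, Lag3 0.0592, Tmem176a −1.08 and Tmem176b −0.84, and salivary gland against liver gave Cd28 −0.93, Emb −1.03, Gpr183 −0.27 and Nfkbia −0.14.

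With the replicate number as a block the counts were 7414, 4407, 3795, 4590, 77, 5734, 2258 and 4288, in the order of the comparisons. Libraries with one replicate number correlated at −0.36 to 0.15 after removing tissue means (13 pairs) and those with different numbers at −0.33 to 0.36 (24 pairs). Where a tissue has 2 libraries their deviations mirror each other, so this cannot tell whether the numbers pair the libraries. In simulated data 16.3% of 2-fold changes were recovered for ILC1 in gut against salivary gland, and depth was not varied there, so its part in this was not tested. Far fewer genes were changed there than the 4951 that passed in the real data, so this share is not the power of the real test.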

Other observations

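The named subsets differed within a tissue, given here as levels without a test, since subsets were made from the same values. In gut, ILC1_LPL2 held Il22 at 12.3 ± 2.20 UMIs per 10000 (SD, n = 3) against 0.0235 ± 0.00265 in ILC1_LPL1, and Rorc at 1.18 ± 0.196 against 0.0315 ± 0.0168. Gzmb, which encodes granzyme B, stood at 2.15 ± 0.702 in ILC1_LPL2 against 18.1 ± 1.99 in ILC1_LPL1. Int_LPL1 has the T cell markers Cd3d and Cd3g among its 10 leading genes. Like NK_LPL1, it has no NK or ILC1 marker of the fixed set among them. Int_LPL1 held Eomes at 1.70 ± 0.151 and Klra4 at 4.002 ± 0.590, while NK_LPL1 held 2.32 ± 0.331 and 5.80 ± 0.462. Int_LPL2 held the heat shock gene Hspa1a at 40.0 ± 5.99 against 4.88 ± 1.38 in Int_LPL1. In liver, ILC1_Liv1 held Cd3g at 21.7 ± 1.42 against 3.32 ± 0.236 in ILC1_Liv2, and Il7r at 0.493 ± 0.0774 against 4.25 ± 0.441. These genes were chosen after their values were seen.

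In salivary gland, Gzmc stood at 30.4 ± 0.529 in ILC1_SG1, 11.3 ± 0.893 in Int_SG1 and 0.206 ± 0.0220 in NK_SG1 (SD, n = 2), and Itgae at 2.90 ± 0.492, 0.951 ± 0.167 and 0.0203 ± 0.00848. Eomes ran the other way, at 0.881 ± 0.123, 2.46 ± 0.238 and 3.41 ± 0.0231. Among NK cells, Ly6c2 stood at 8.05 ± 0.963 in NK_Liv1 against 1.61 ± 0.378 in NK_Liv2, and at 8.80 ± 2.13 in NK_Sp1 against 2.14 ± 0.815 in NK_Sp2. NK_Liv3 and NK_Sp3 both held Srm, a polyamine synthesis gene, at 1.11 ± 0.182 and 1.11 ± 0.386.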
